A study of Drosophila melanogaster with 18 samples.

How the data were processed

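Small RNA was sequenced from Drosophila Schneider 2 (S2) cells, a line of embryonic origin, that carried a knockout of Ago2, the Argonaute protein that binds siRNAs and some miRNA arms. Per the labels' protocols, the cells were grown at 25 °C in Schneider's medium with 10% serum, were passaged every 3 days, and received 500 µM 4-thiouridine (s4U) for 5, 15, 30 or 60 min or for 3, 6, 12 or 24 h before lysis. Total RNA of the labelled cells was then treated with iodoacetamide (IAA), which alkylates s4U so that reverse transcription reads it as C. A T-to-C (T>C) mismatch therefore marks RNA made after s4U was added. The control had neither s4U nor IAA. RNA of 18 to 30 nt was selected, 2S rRNA was depleted and both adapters carried 4 random bases at the ligation site, per the labels' protocols. Each of the 9 groups had 2 biological replicates, 18 libraries in all, and per the series description each replicate was prepared as 1 library batch, so the replicate number is also the batch.

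Per the submitters' processing notes, Picard, cutadapt 1.7.1 and Bowtie 1.2.2 were used with genome build dm6. Per the series description, an in-house small RNA workflow was run on each replicate separately and on merged replicates. The role of each tool is not stated. The deposited mutation tables give, per the file headers, the count of reads showing each base at each position of a miRNA arm, without normalization, and the library tables give the small RNA and miRNA read counts of each library. The deposited length and position tables give a signal per arm, which from the values is ppm of the small RNA reads of the library as normalized by the authors, for all reads and for reads with a T>C mismatch. Multiplied by the library's small RNA reads, 100% of the length values and 100% of the position values gave whole reads within a tolerance of 0.001, and 100% of the recovered arm totals equalled the count at position 1 of the mutation table. From the values, reads that match several arms appear to be counted at each of them.

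The per-replicate tables were used for all tests and the merged tables only as an alternative. The mutation tables of the first and second replicate held 111 and 113 arms, of which 111 were in both. From the values, the authors kept arms with an average of at least 5 ppm. The position tables held 277 and 222 arms, of which 208 were in both. T>C conversion of an arm was the number of T>C mismatches over the coverage of its T positions among positions 1 to 18 of the read, counted from the read's 5′ end. The 18-nt limit was set after the layout of the files was known, because every read covers those positions. A mean of at least 100 reads per library was required, which all 110 arms with a T in that window met. Background-subtracted values have the no-s4U value of the same replicate removed. In each of 72 precursors the arm with the higher mean ppm in the 2 no-s4U libraries was called the guide and the other the passenger, and all 72 guides and 39 passengers carried the authors' matching annotation as mature or star. In 39 precursors both arms were measured. 11 arms share their first 18 nt with another arm. The values of miR-13b-1-3p and miR-13b-2-3p, of miR-276a-5p and miR-276b-5p, and of miR-281-1-3p and miR-281-2-3p are nearly identical, so these cannot be told from their copy, while those of miR-2a, miR-2b and miR-2c differ. Arm names are those of the authors. Hairpin coordinates are dm6 positions from the Ensembl annotation in the same coordinate system, matched by FlyBase identifier for 70 of the 72 precursors.

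Abundance was tested on the recovered reads of the 111 arms with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F-test) in 1 fit over all 18 libraries with the group as the only term, and Benjamini-Hochberg adjusted p under 0.05 was required. Conversion above no s4U was tested with limma 3.58.1 (eBayes with trend) on log2(fraction + 0.001), so that log2 changes of arms with little label are understated. Adjusted p-values were taken within each of the 8 times. Paired differences between arms or between read classes were tested with 2-sided sign-flip permutation tests across precursors or arms, other differences with 2-sided permutation tests (100000 permutations), and correlations with permutation tests, exact within a replicate. The 39 precursors and 110 arms come from the same 18 libraries and are not independent replicates. Half-lives came from least-squares fits of P(1 - exp(-kt)) to the background-subtracted conversion, with P the plateau, k the rate and t the time in h. A fit with R2 under 0.8 or a half-life above 48 h was left as not determined. The planned fit took both replicates with 1 plateau per arm, and each replicate was also fitted alone. A fit with 1 rate and a plateau for each replicate was added after the data were seen. Length differences compare the mean length of T>C reads with that of all reads of an arm and needed at least 1 T>C read in each library of that time. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

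Main tests, arm lists and the rule for named arms were written before the data were examined. The rule names the 10 most abundant arms without s4U, the 10 shortest and 10 longest half-lives, the 5 arms per direction with the lowest adjusted p in each abundance contrast, the 5 precursors with the largest and the 5 with the smallest guide minus passenger conversion at 60 min and at 24 h, the 5 arms per direction with the largest length difference at 60 min, the first 5 arms by adjusted p at the earliest time with any arm above no s4U, and measured members of the lists. The lists were the mirtrons, the let-7 complex, the K-box family, arms known to enter Ago2 in wild-type cells, arms trimmed by Nibbler, 6 genomic clusters, and arms typical of muscle, nervous system, early embryo and germ line as markers of other cells. Alternatives planned at the same time were DESeq2's size factors and test, no filter on low counts, the replicate as a block, other pseudocounts and read minimums, a quasi-binomial model, other half-life settings, the merged tables and leaving out each library or replicate.

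Libraries held 6230382 to 55209992 small RNA reads, and the T coverage summed over an arm's window was at least 35 in every library. Intervals of a share of reads are 95% Wilson intervals. Values are means of 2 replicates with the standard deviation (SD), and those errors and counting limits cover these libraries only, since PCR copies were not marked. In abundance, same-numbered libraries deviated together only in part, while conversion was lower in the second replicate at every labelled time. The correlation of their abundance deviations from the group means had a median of 0.255 over 36 pairs of groups (range -0.600 to 0.845). No component of abundance among the first 4 separated the replicates. The pairing used for the blocked fits comes from the stated library batches. On counts simulated for the 24 h against no s4U contrast with 20 of 111 arms changed, edgeR recovered 2 arms at a fold of 2, 18 at 4 and 18 at 8, with 1, 2 and 0 false calls. For conversion at 24 h against no s4U, limma recovered 0, 10, 18 and 18 of 20 changed arms of 110 at folds of 2, 4, 20 and 100. Those simulated conversions had noise of a set size and no shift between replicates, so the lower label of the second replicate was not covered. The half-life fit, tested on simulated data for 110 arms, returned medians of 0.500, 3.01, 11.8 and 23.4 h for true values of 0.5, 3, 12 and 24 h. Both simulated replicates had the same plateau and only counting noise, so a plateau difference between replicates, as found here, was not covered. Arms outside the mutation tables, other small RNA classes and the Ago2 locus itself were not analysed here except where stated, and small RNA reads cannot check the knockout.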

Results

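The series asked how miRNA arms are made and lost in S2 cells without Ago2, by following s4U into mature miRNAs over 24 h. It held 18 small RNA libraries, 2 for each of 9 groups: no s4U, and s4U for 5, 15, 30 or 60 min and 3, 6, 12 or 24 h. In the first replicate, libraries had from 18521949 (12 h) to 55209992 (no s4U) small RNA reads. The second replicate had 18682828 to 31128759 reads from no s4U to 60 min and 6230382 to 8106727 from 3 h to 24 h. The miRNA share of these reads ranged from 56.9% to 69.4%. Reads with a T>C mismatch made up 0.128% (0.127 to 0.129, counting error only) and 0.0982% (0.0965 to 0.0999) of the reads of the 111 arms in the no-s4U libraries of the first and second replicate, and 16.9% (16.9 to 16.9) and 8.94% (8.91 to 8.97) at 24 h.

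The cells were dominated by a few guide arms. bantam-3p, from a growth-promoting miRNA locus (FBgn0262451, chromosome 3L, 642208 to 642288, dm6, within the noncoding gene lncRNA:CR43334), had 400949 ± 81387 ppm without s4U (SD, n = 2). miR-184-3p (chromosome 2R, 13329402 to 13329501, within lncRNA:CR44206) had 61907 ± 11903 ppm and miR-14-3p (chromosome 2R, 9553762 to 9553824, within lncRNA:CR43651) had 23258 ± 4256 ppm. The rest of the 10 most abundant arms were miR-2a-1-3p, miR-2a-2-3p, miR-2b-1-3p, miR-2b-2-3p, miR-8-3p, miR-13b-1-3p and miR-13b-2-3p. Of these, miR-8-3p ranged widely, from 25668 ppm in the first no-s4U library to 2576 ppm in the second. The 2 copies of miR-2a, of miR-2b and of miR-13b have nearly the same values, so that they are not separate measurements. Markers of other cells were near the floor: the median of muscle miR-1-3p was 0.774 ppm in the first replicate and 0.915 ppm in the second, and that of neural miR-124-3p was 0.408 and 2.89 ppm. The early embryonic arms miR-3-3p, miR-4-3p, miR-5-5p, miR-6-1-3p, miR-6-2-3p, miR-6-3-3p, miR-286-3p and miR-309-3p, and miR-310-3p to miR-313-3p of the germ line, had medians of at most 4.37 ppm. let-7-5p had medians of 0.754 and 0.633 ppm and miR-125-5p 0.288 and 0.263 ppm, so that 0 members of the ecdysone-induced let-7 complex were measured among the 111 arms.

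Conversion rose above no s4U first in passenger arms and in most guides later. It is a share of an arm's molecules, so a large unlabelled pool lowers it, and it does not show in which arm label arrived first. Among molecules labelled within 15 min, counted as given further below, the median log2 guide to passenger ratio was 0.52 over 33 precursors. The passenger was ahead in 8 of them. At 5 min 4 of 110 arms were above no s4U and all 4 were passengers, in a comparison that asks when conversion first passes no s4U. At 15 min 32 of 39 passengers but only 3 of 71 guides had passed, at 60 min 32 passengers and 22 guides, and at 24 h 37 passengers and 66 guides. With the replicate as a block, 20 passengers and 1 guide (miR-276b-5p) passed at 5 min, 33 and 14 at 15 min, 34 and 46 at 60 min, and 37 and 67 at 24 h. The median conversion of passengers rose from 0.0290% without s4U to 0.168% at 5 min, 1.16% at 15 min and 2.53% at 60 min. That of guides was 0.0314% without s4U, 0.0393% at 5 min, 0.0672% at 15 min and 0.186% at 60 min, and reached 2.98% at 24 h against 4.34% for passengers. The 4 arms at 5 min were miR-14-5p, miR-184-5p, miR-275-5p and miR-308-5p. miR-14-5p had 1.68% ± 1.05 (SD, n = 2) against 0.0303% without s4U, a log2 change of 3.63 ± 0.61 (SE; limma adjusted p = 0.00269), from a T coverage of at least 5621 per library. miR-275-5p (FBgn0262453, chromosome 2L, 7425795 to 7425892, within lncRNA:CR43857) had 0.935% ± 0.524 (limma adjusted p = 0.00844), miR-184-5p 0.840% ± 0.350 (limma adjusted p = 0.00385) and miR-308-5p 0.452% ± 0.246 (limma adjusted p = 0.0390). The 3 guides at 15 min, picked out after their values were seen, were miR-12-5p, miR-308-3p and miR-276b-5p, the last of which shares its first 18 nt with the passenger miR-276a-5p. By list, 1 arm of miR-275/miR-305 had passed at 5 min (2 adjusted over the list alone), and 0 of miR-306/miR-79/miR-9b/miR-9c and 0 of miR-279/miR-996 (1 and 1 over the list alone).

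**Figure D1:**
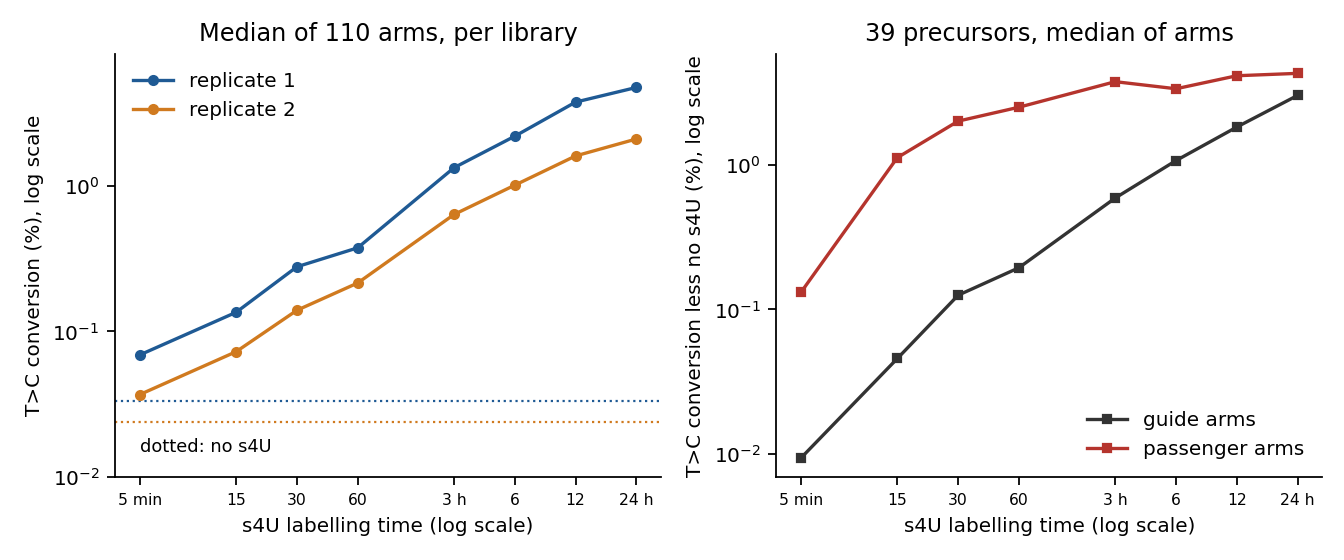
The left panel plots the median T>C conversion of 110 arms (%, log scale) of each library against s4U labelling time (log scale), with 1 line per replicate and the no-s4U value dotted. The right panel plots the median background-subtracted conversion (%, log scale) of the guide and passenger arms of 39 precursors, where passengers lie at 2.50% and guides at 0.194% at 60 min.

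Over all 110 arms the number above no s4U (limma, adjusted p under 0.05) was 4, 35, 42, 54, 92, 102, 105 and 103 from 5 min to 24 h, and 0 arms were below no s4U at any time. With the replicate as a block the counts were 21, 47, 69 and 80 from 5 min to 60 min. The 5 min count rested on 2 libraries: it was 0 without the first 5 min library and 1 without the second no-s4U library. A quasi-binomial model of the counts called 0 arms up to 3 h and 55 at 24 h, so the early calls depend on the test. 7 arms did not pass at 24 h: miR-281-1-5p, miR-1009-5p, and 5 arms with bases that differed from the reference in every library, miR-13a-3p, miR-303-5p, miR-4940-5p, miR-4962-3p and miR-4962-5p. In miR-13a-3p a T13C difference (position counted from 1 at the read's 5′ end) stood in 51.6% of reads and its conversion was 8.64% without s4U and 9.71% ± 3.06 at 24 h.

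Label rose with time in each replicate. The median conversion of the 110 arms in the first and second replicate was 0.0331% and 0.0237% without s4U, 0.0690% and 0.0369% at 5 min, 0.375% and 0.215% at 60 min, 1.33% and 0.635% at 3 h, and 4.73% and 2.09% at 24 h, which is 143-fold and 88.2-fold over no s4U. Across the 16 labelled libraries it correlated with log2 time (r = 0.810, permutation p = 4e-05, adjusted p = 9.16e-05; rho = 0.959, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 8e-05; family of 24). Without the 2 libraries farthest from the median time r was 0.826. Within the first replicate r was 0.918 (exact p = 0.000595) and within the second 0.927 (exact p = 0.000471), and rho was 1 in each (exact p = 4.96e-05). The gain was in T>C: its median rose by 3.38 ± 1.85 percentage points from no s4U to 24 h (SD, n = 2), while the largest mean rise among the other 11 kinds was 0.0176 points. Rank correlation of T>C with time was 1 in each replicate (exact p = 4.96e-05, adjusted p = 0.000595 over 12 kinds). In the first replicate C>T went from 0.0494% to 0.0866% and G>T from 0.0333% to 0.0658% (rho = 0.929, exact p = 0.00223, adjusted p = 0.00893 for each). In the second they were 0.0463% and 0.0444%, and 0.0479% and 0.0241%. G>C (rho = 0.905, exact p = 0.00456, adjusted p = 0.0137) and G>A (rho = 0.881, exact p = 0.00724, adjusted p = 0.0174) also rose with time in the first replicate. Neither passed in the second (rho = -0.731 and -0.667). A>T fell with time in the second replicate (rho = -0.881, exact p = 0.00724, adjusted p = 0.0435) and did not pass in the first (rho = 0.476).

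Both arms of a precursor are released from it together, and the comparison of arms asks whether they carry label alike afterwards. At 60 min conversion was higher in the passenger than in the guide in 34 of 39 precursors. Medians were 2.50% for passengers and 0.194% for guides after subtraction of no s4U. The mean guide minus passenger difference was -2.57 percentage points (SE 0.412, sign-flip permutation p = 1e-05), -3.22 in the first replicate and -1.92 in the second. The difference was already -0.220 points at 5 min (SE 0.0511, passenger higher in 34) and -1.34 at 15 min (SE 0.220, passenger higher in 37), each with permutation p = 1e-05. It then shrank to -1.11 points at 12 h (SE 0.441, permutation p = 0.0161, adjusted p = 0.0184 over 8 times). At 24 h the passenger was higher in 25 of 39 precursors and the mean difference of -0.344 points (SE 0.437, permutation p = 0.457) did not hold up. In the 25 precursors whose arms both had at least 1000 reads it was -0.933 points (SE 0.362, permutation p = 0.0164).

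miR-14 had the widest gap at 60 min: miR-14-5p was at 9.79% ± 4.54 and miR-14-3p at 0.116% ± 0.0515 (SD, n = 2), a difference of -9.67 points. miR-275 (-8.63 points), miR-965 (-6.25), miR-79 (-5.69) and miR-279 (-5.38) followed. The order was turned in miR-276b (3.47 points), miR-308 (0.483), miR-190 (0.405), miR-9c (0.331) and miR-281-2 (0.0489). In miR-308 this was less than the spread of its guide at 60 min. Arms of miR-276b and miR-281-2 share their 18 nt with other arms. miR-308-3p, a guide of the K-box family from an intron of the ribosomal protein gene RpS23 (FBgn0262407, chromosome 2R, 14215802 to 14215864), was at 2.67% ± 1.18 at 60 min and 13.9% ± 7.70 at 24 h, against 2.19% ± 0.174 and 2.84% ± 1.03 for miR-308-5p. Its gap of 11.1 points was the widest with the guide ahead at 24 h, before miR-9c (3.79), miR-276b (3.40), miR-190 (2.42) and miR-277 (2.24). The passenger was farthest ahead at 24 h in miR-14 (-4.72 points), miR-79 (-3.98), miR-307a (-3.17), miR-304 (-3.14) and miR-8 (-3.01).

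**Figure D2:**
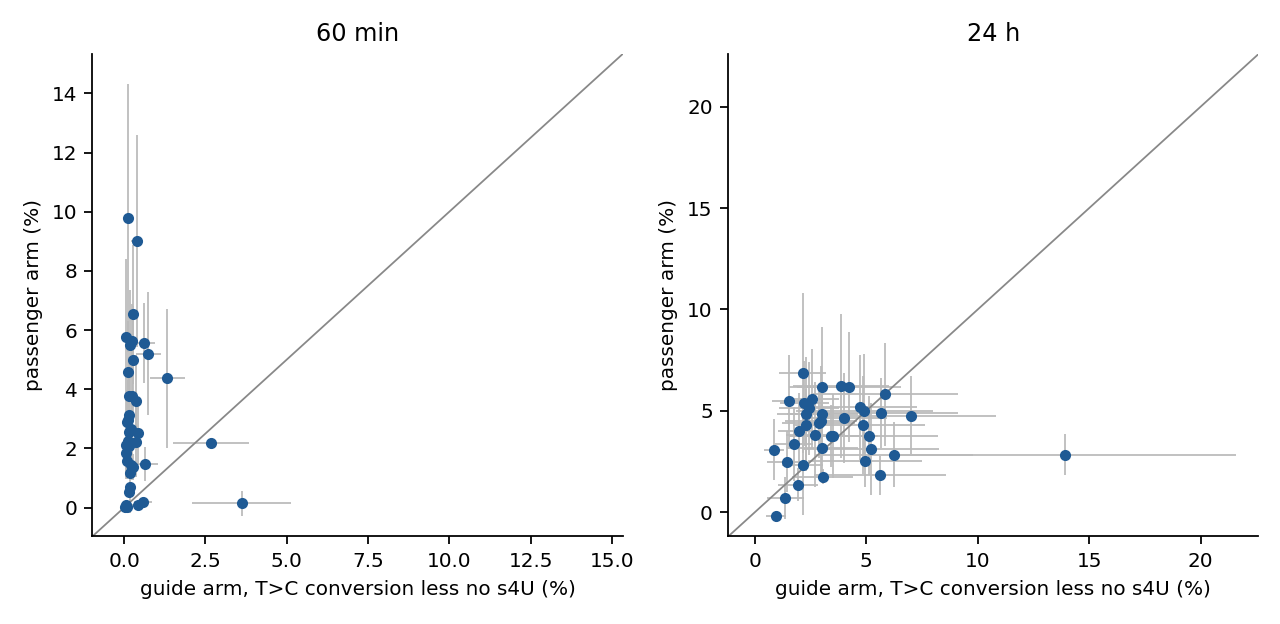
Each point is 1 of 39 precursors, with the background-subtracted T>C conversion (%) of its guide on the x axis and of its passenger on the y axis, at 60 min (left) and 24 h (right). Bars are the SD of 2 replicates and the line marks equal values; 34 precursors lie above it at 60 min and 25 at 24 h.

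Fitted half-lives were short in most passenger arms and many hours long in most guides, in a comparison that asks how fast label replaces each arm. The cells were grown and passaged, so dilution by growth may be part of each rate. Decay was not measured apart from it. The fit also takes the level of each arm as constant over the labelling. The fitted curve can only rise to a constant plateau, whereas conversion in some passengers, named further below, was lower again at the last time. The curve holds no delay before label arrives and rises at most in proportion to time. Median passenger conversion rose more steeply, from 0.131% at 5 min to 1.12% at 15 min. Half-lives well under 1 h can therefore not be told apart from such a delay. Fitted in each replicate alone, passengers had a median half-life of 0.495 h in the first replicate and 0.446 h in the second, and guides 12.8 h and 9.40 h. These guide medians leave out 12 and 15 guides with fitted values above 48 h, and with those counted they were 14.6 h and 13.4 h. Half-lives were determined for 91 and 74 of 110 arms, with medians of 7.98 and 6.86 h over both kinds of arm. For the 67 arms determined in each, the log2 half-lives of the replicates correlated across arms with r = 0.974 and rho = 0.946 (permutation p = 1e-05 for each; arms are not independent replicates), with a median ratio of 0.839 of the second to the first. The distance between passengers and guides can raise this correlation, and arms not determined in both replicates are left out of it. No correlation within guides or within passengers is given here. Fitted plateaus were 6.53% in the first replicate and 2.98% in the second. The planned fit of both replicates with 1 plateau per arm described these data poorly. It determined 21 arms, with a median of 16.7 h, and left out 81 for R2 under 0.8 and 8 above 48 h.

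With a plateau for each replicate, chosen after seeing the data, 92 arms were determined with a median of 7.86 h, and 28 of them had half-lives under 1 h. There the 57 guides had a median of 12.8 h (15.0 h with 9 guides above 48 h counted) and the 35 passengers 0.482 h. The shortest were passengers: miR-14-5p at 0.134 h (SE 0.0291), miR-275-5p at 0.149 h (SE 0.0378), miR-13b-2-5p at 0.196 h, miR-184-5p at 0.204 h, miR-965-5p at 0.209 h, miR-308-5p at 0.215 h, miR-79-5p at 0.224 h, miR-12-3p at 0.251 h, miR-279-5p at 0.251 h and miR-11-5p at 0.253 h. The longest were guides: miR-263a-5p at 40.0 h (SE 18.2), miR-1008-3p at 39.4 h (SE 12.1), miR-2535b-5p at 38.6 h (SE 12.1), miR-284-3p at 32.9 h (SE 33.0), bantam-3p at 30.0 h (SE 5.45), miR-318-3p at 26.7 h (SE 9.62), miR-4962-5p at 26.2 h (SE 24.9), miR-283-5p at 22.4 h, miR-998-3p at 20.4 h and miR-1007-3p at 19.9 h. Values near or above the 24 h of labelling have wide errors, and the first and second replicate fitted alone differed widely for most of these arms. They gave 51.3 and 19.9 h for miR-263a-5p, 46.7 and 20.1 h for miR-1008-3p, 52.4 and 15.9 h for miR-2535b-5p, 22.2 and 658 h for miR-284-3p, 25.2 and 233 h (SE 367) for bantam-3p, 40.4 and 6.65 h for miR-318-3p, and 482 and 6.79 h for miR-4962-5p, which was not above no s4U at 24 h. Values above 48 h count as not determined.

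In the planned fit the shortest half-lives were those of miR-307a-5p (5.63 h, SE 2.12), miR-996-3p (6.29 h, SE 2.13), miR-999-3p (6.84 h, SE 3.22), miR-279-3p, miR-2279-3p, miR-970-3p, miR-8-3p, miR-11-3p, miR-79-3p and miR-306-5p. The longest were those of bantam-3p (35.2 h, SE 60.2), miR-263a-5p (34.1 h, SE 57.8), miR-968-5p (22.7 h, SE 25.1), miR-283-5p, miR-998-3p, miR-1003-3p, miR-9b-5p, miR-1007-3p, miR-307a-3p and miR-33-5p. Only the precursor miR-307a had both arms determined in that fit, with a log2 guide to passenger ratio of 1.60 and no test. In the first replicate alone the mean log2 ratio was 3.94 over 31 precursors and in the second 4.03 over 21. With a plateau for each replicate it was 3.98 (SE 0.418, sign-flip permutation p = 1e-05, 31 precursors). Half-life and abundance showed no relation that held up, in the planned fit (r = 0.193, permutation p = 0.399, adjusted p = 0.855; rho = 0.0429, permutation p = 0.855; 21 arms, family of 4 p-values) nor in the replicates (r = 0.156 over 91 arms and 0.169 over 74), and r was -0.145 without the 2 farthest arms. For passengers alone r was -0.339 in the first replicate (permutation p = 0.0459, not adjusted; rho = -0.196, permutation p = 0.259; 35 arms), -0.188 in the second (permutation p = 0.364; 25 arms) and -0.349 with a plateau for each replicate (permutation p = 0.0397, not adjusted; rho = -0.186, permutation p = 0.283; 35 arms).

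**Figure D3:**
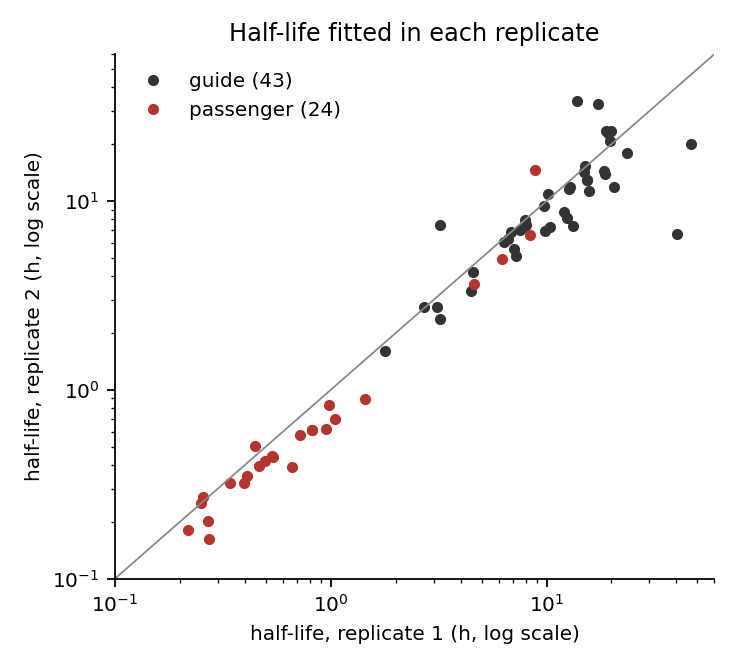
Each point is 1 of 67 arms whose half-life (h, log scales) was determined in the first replicate (x axis) and in the second (y axis) fitted alone, with 43 guides in black and 24 passengers in red. The line marks equal values; passengers gather below 1 h and guides above it.

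Among the lists, the arms known to enter Ago2 in wild-type cells differed by role: the passengers bantam-5p and miR-276a-5p had half-lives of 0.878 h (SE 0.114) and 0.770 h (SE 0.0891) and the guide miR-277-3p 4.50 h (SE 0.176), with a plateau for each replicate, as for all half-lives of lists. All 3 were above no s4U at 60 min and at 24 h (3 and 3 adjusted over the list alone), and 0 at 5 min (2 adjusted over the list alone). The Nibbler-trimmed guides miR-34-5p (6.30 h), miR-305-5p (9.24 h) and miR-263a-5p were above no s4U in 2 of 3 cases at 60 min (2 adjusted over the list alone) and 3 of 3 at 24 h (3 over the list alone).

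The 10 guides of the K-box family, whose seeds pair with the K box motif, had a median conversion of 0.202% at 60 min and 2.90% at 24 h, beside 0.186% and 2.98% for all guides. Of these 3 were above no s4U at 60 min (1 adjusted over the list alone) and 9 at 24 h (9 over the list alone), all but miR-13a-3p. miR-308-3p (3.03 h, SE 0.442) was the fastest of the 8 determined, miR-2b-1-3p and miR-2b-2-3p had 7.78 and 7.47 h, and miR-11-3p and the miR-13b arms 14.8 and 14.9 h. Mirtrons, which leave short introns by splicing and not by Drosha cleavage, gave 9 arms. Of these 3 were above no s4U at 60 min (3 adjusted over the list alone) and 8 at 24 h (9 over the list alone). They were led by the passengers miR-1003-5p (2.99% ± 1.39 at 60 min) and miR-1012-5p (1.52% ± 0.535) and the guide miR-1012-3p (0.679% ± 0.399). The median of the 7 mirtron guides at 60 min was 0.0601% and that of 64 other guides 0.154% after background subtraction, a difference of -0.0942 points that did not hold up (permutation p = 0.184, adjusted p = 0.245 over 4 times).

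Clusters hold several precursors near each other in the genome, and the fitted half-lives given here differed between their arms, without a test of that difference. In the miR-277/miR-34/miR-317 cluster all 6 arms were above no s4U at 60 min and at 24 h (6 and 6 adjusted over the list alone). Its guides miR-277-3p, miR-34-5p and miR-317-3p had half-lives of 4.50, 6.30 and 11.5 h and its passengers miR-277-5p, miR-34-3p and miR-317-5p 0.259, 0.953 and 0.379 h. The 4 arms of miR-275/miR-305 (4 at 60 min and 4 at 24 h, 4 and 4 over the list alone) and the 3 of miR-279/miR-996 (3 and 3, 3 and 3 over the list alone) had all passed by 60 min. Of miR-12/miR-283/miR-304, 4 of 6 arms had passed at 60 min and 6 at 24 h (4 and 6 over the list alone), with miR-12-5p at 1.74 h beside miR-283-5p at 22.4 h. Of miR-11/miR-998, 2 of 4 passed at 60 min and 4 at 24 h (2 and 4 over the list alone), and of miR-306/miR-79/miR-9b/miR-9c, 5 of 8 at 60 min and 8 at 24 h (5 and 8 over the list alone).

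Whether miRNA levels held while the cells took up s4U was asked of the read counts. Against no s4U, 6 arms were higher and 24 lower at 24 h among 111 (edgeR, adjusted p under 0.05). Of the lower arms 15 were passengers and 9 guides, and of the higher ones 1 was a passenger and 5 were guides. The lower arms included miR-980-5p (log2 change -2.92 ± 0.29, SE; edgeR adjusted p = 2.39e-05), miR-306-3p (-2.68 ± 0.67), miR-277-5p (-2.19 ± 0.55), miR-190-5p (-1.95 ± 0.44) and miR-92b-3p (-1.92 ± 0.48), each of the last 4 at an edgeR adjusted p of 0.0189. The higher ones were led by miR-277-3p (2.35 ± 0.39, edgeR adjusted p = 0.00316), with miR-308-3p (1.82 ± 0.42), miR-190-3p (1.71 ± 0.43), miR-1007-3p (1.21 ± 0.30) and miR-279-3p (1.29 ± 0.37). IAA treatment differs along with s4U in this contrast. The median change over all arms was -0.28 on the log2 scale with TMM and -0.12 with DESeq2's size factors, which called 7 arms higher and 19 lower. DESeq2's own test called 12 higher and 27 lower.

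The second no-s4U library stood apart from the other 17. bantam-3p took 66.8% of the reads of the 111 arms there and 36.1% to 48.7% in every other library, and the library lay at -17.1 on the first principal component (57.0% of variance) against -1.51 to 2.85 for the others. The 24 lower arms had fallen by a median of 2.78 on the log2 scale at 24 h in the second replicate (24 of 24 lower) and by 0.23 in the first (19 of 24 lower). Without that library 12 arms differed between 24 h and no s4U, without the first no-s4U library 70, without the first 24 h library 9 and without the second 2. With a replicate block and without the second no-s4U library, chosen after seeing the data, 7 were higher and 11 lower.

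**Figure D4:**
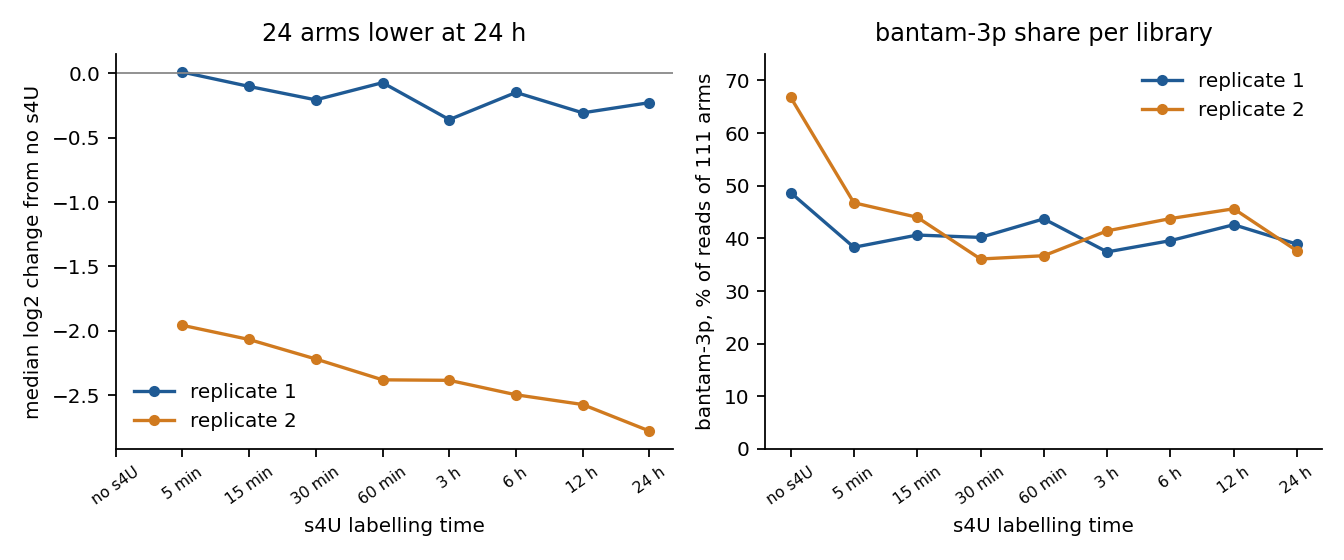
The left panel plots the median log2 change from no s4U of the 24 arms lower at 24 h against s4U labelling time, with 1 line per replicate, from 0.01 to -0.23 in the first and from -1.96 to -2.78 in the second. The right panel plots the share of bantam-3p among the reads of 111 arms (%) in each library, 66.8% in the second no-s4U library.

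Between 24 h and 5 min, both with IAA, 6 arms fell: miR-980-5p (log2 change -2.14 ± 0.28, SE; edgeR adjusted p = 0.000497), miR-190-5p (-1.87 ± 0.44), miR-1002-5p (-1.32 ± 0.34), miR-12-5p (-1.16 ± 0.28), miR-1012-3p (-1.01 ± 0.25) and miR-79-5p (-0.98 ± 0.25), the last 5 at an edgeR adjusted p of 0.0362. No arm passed as higher; 19 arms had an unadjusted p under 0.05 in either direction, DESeq2's test called 1 higher, and the blocked fit 2. Few list members passed: 1 of 9 mirtrons fell (miR-1012-3p; 1 adjusted over the list alone), 1 of 6 arms of miR-12/miR-283/miR-304 (1 over the list alone) and 1 of 8 of miR-306/miR-79/miR-9b/miR-9c (1 over the list alone), and 0 arms of the other lists passed over all arms. Median log2 changes of lists ranged from -0.54 (miR-12/miR-283/miR-304) to 0.54 (K-box family). Over the list alone 1 of the 3 Ago2-loaded arms, miR-277-3p, was higher, with a log2 change of 1.10 ± 0.38. Against no s4U at 24 h, 2 mirtrons were higher (miR-1007-3p and miR-1009-5p; 2 adjusted over the list alone, with miR-1003-5p lower there, log2 change -1.76 ± 0.63), as was 1 K-box arm (miR-308-3p; 1 over the list alone), 1 Ago2-loaded arm was higher and 1, bantam-5p, lower (1 and 1 over the list alone). In the clusters, miR-277/miR-34/miR-317 had 1 higher and 2 lower (2 and 2 over the list alone), miR-11/miR-998 2 lower (2), miR-306/miR-79/miR-9b/miR-9c 2 lower (3), miR-279/miR-996 1 higher (1), and the Nibbler list, miR-275/miR-305 and miR-12/miR-283/miR-304 had 0 (0 over each list alone).

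Any difference among the 9 groups passed for 9 arms: miR-980-5p, miR-1012-3p, miR-190-5p, miR-277-5p, miR-14-5p, miR-79-5p, miR-306-3p, miR-308-3p and bantam-5p (edgeR, adjusted p from 0.000102 to 0.0283). With a replicate block the number was 4 and with DESeq2's test 35. It was 60 without the first no-s4U library, 15 without the second, and 1 without any of the 10 libraries of 15 min, 30 min, 60 min and 3 h or the second of 12 h and of 24 h. The count of 6 between 24 h and 5 min was 12 and 14 without the first and second no-s4U library and 1 without any of those 10 or of the first 24 h and second 5 min library. It was 2 without the first 5 min or the first 6 h library.

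Reads that carried label were longer than the arm's reads as a whole, a comparison of young molecules with the whole pool. At 60 min T>C reads were longer by a mean of 0.246 nt (SE 0.0347; longer in 87 of 101 arms; sign-flip permutation p = 1e-05), by 0.255 in the first replicate and 0.238 in the second, and at 24 h by 0.185 nt (SE 0.0215; longer in 93 of 105 arms; permutation p = 1e-05). Without s4U, T>C reads were shorter by the same measure, at -0.145 nt (SE 0.0625, permutation p = 0.00339, 76 arms), and at 5 min the difference was 0.0518 nt (SE 0.0296, permutation p = 0.0831). Arms are not independent replicates. The Nibbler substrate miR-34-5p (chromosome 3R, 10100936 to 10101034) led at 60 min, with labelled reads of 23.9 ± 0.0425 nt and all reads of 22.6 ± 0.0596 nt, a difference of 1.28 ± 0.0171 nt (SD, n = 2) that was 0.431 ± 0.0178 nt at 24 h. miR-317-3p was longer by 1.16 ± 0.134 nt and miR-2b-2-3p by 1.04 ± 0.0328 nt, each from over 1000 labelled reads per library, miR-2b-2-3p being 1 of 2 copies with nearly the same values. miR-4939-5p (1.24 nt) and miR-966-5p (1.08 nt) rested on at most 8 labelled reads per library. Labelled reads were shortest against the pool in miR-13a-3p (-0.537 ± 0.305 nt), whose T>C reads include the constant difference, in miR-281-1-3p and miR-281-2-3p (-0.463 ± 0.0855 nt, shared reads), in miR-375-3p (-0.408 nt) and in miR-1009-5p (-0.178 nt), the last 4 with at most 9 labelled reads per library.

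**Figure D5:**
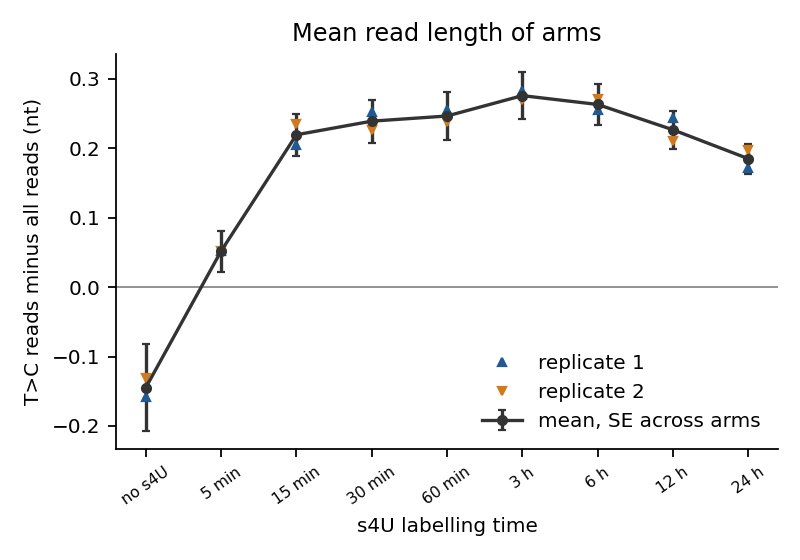
The mean length of T>C reads minus that of all reads of an arm (nt) is plotted for no s4U and each s4U labelling time, as the mean over 76 to 107 arms with its SE across arms (black) and for each replicate (triangles). The difference is -0.145 nt without s4U, 0.276 nt at 3 h and 0.185 nt at 24 h.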

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

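The tests of sequencing errors and of molecule age behind the read lengths, both tests of the replicate difference, and the tests of bantam-3p and of alkylation behind the lower arms were chosen only after the results they measure were seen. The test of the arm difference between 60 min and 24 h and the length test of guides against passengers were not planned either.

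The gap between guide and passenger differed between times: guide minus passenger conversion was lower at 60 min than at 24 h by a mean of -2.22 percentage points (SE 0.417, sign-flip permutation p = 1e-05, the smallest the permutations can give), below 0 in 31 of 39 precursors. The excess length of labelled reads differed between kinds of arm at 24 h: it was 0.235 nt (SE 0.0296) in 68 guides and 0.0928 nt (SE 0.0211) in 37 passengers, a difference of 0.142 nt (permutation p = 0.00122), while at 60 min the difference was 0.0853 nt (permutation p = 0.238). Label also appeared in data outside the main measurement: in 97 arms outside the mutation tables, T>C reads averaged 15.9% at 24 h, with 21.4% (20.1 to 22.9, counting error only) and 10.4% (8.73 to 12.2) in the first and second replicate against 3.83% (3.44 to 4.26) and 6.86% (5.84 to 8.04) without s4U, from 3245 and 1159 reads at 24 h and 8328 and 2042 without s4U, while at 60 min the share was 7.29% in the first replicate and 5.01%, below no s4U, in the second.

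Labelled reads of an arm were longer than all its reads by 0.246 nt at 60 min. A higher chance of a T in a longer read gave a computed excess of 0.0246 nt, and the observed excess was larger by 0.222 nt (SE 0.0340), which argues against T content as the whole cause. Sequencing errors read as T>C are argued against too, since T>C reads without s4U were shorter than the pool, at -0.145 nt (SE 0.0625). A candidate explanation that stays open is that young molecules are longer than the pool: in 100 arms measured at both times the excess was larger at 60 min than at 24 h by 0.0745 nt (SE 0.0266, sign-flip permutation p = 0.00573), higher in 66. The excess was however largest at 3 h (0.276 nt) and only 0.0518 nt at 5 min, and trimming itself was not measured.

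Label was lower in the second replicate than in the first at every labelled time, with a median conversion at 24 h of 2.09% against 4.73%. The tables argue against slower turnover in the second replicate for the arms as a whole: the median ratio of its half-lives to those of the first was 0.848 over all 110 arms, determined or not (interquartile range 0.676 to 1.05), though above 1 in 32 arms, bantam-3p and miR-2a-1-3p among them. Lower uptake or alkylation of s4U in that batch may account for the difference, since the median ratio of fitted plateaus was 0.465. Uptake and alkylation were not tested apart. The design gives no biological difference between the replicates, and no biological explanation beyond those named here was tested.

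In the read counts 24 arms were lower at 24 h than without s4U. With bantam-3p left out 22 arms were lower. TMM scaling already allows for a dominant arm, so this test cannot decide whether bantam-3p taking most reads of a library plays a part. That the second no-s4U library stands apart may account for most of the pattern: the median change to 24 h was -0.23 within the first replicate (interquartile range -0.57 to -0.04) and -2.78 within the second (-3.10 to -2.24). Alkylation alone cannot be told apart from this with 1 no-s4U library in each replicate: at 5 min the median change was already -1.96 in the second replicate, but 0.00995 in the first (interquartile range -0.36 to 0.17). A response of the cells to 24 h of s4U stays open too and was not tested apart from alkylation.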

How the results depend on the processing

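Chosen only after the data were seen were the fits without the second no-s4U library or on labelled libraries alone, bantam-3p left out, all read positions, the T>C read share, arms without shared or constantly differing sequence, at least 20 labelled reads, arm kinds apart, and a plateau for each replicate. The cause was not tested for any change below.

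The 2 replicates per group leave the arm counts dependent on single libraries, and a library left alone in its group is assumed to vary like the other groups. The guide and passenger gap at 60 min (10 alternatives), the longer labelled reads at 60 min and 24 h (9 each), the rise of label with time (3), the specificity for T>C (2) and the absence of a mirtron difference (6) kept their direction and their side of the threshold. The guide and passenger difference at 24 h did so in 9 alternatives and passed at a mean of at least 1000 reads (-0.933 points, SE 0.362, permutation p = 0.0164, 25 precursors). Among named arms and list members 0 called values reversed, 8 conversions moved beyond their spread with all read positions (that of miR-1016-3p at 60 min to below 0), and 5 half-lives did without the first replicate. With the replicate as a block, 163 of their values in the 2 abundance contrasts kept their side, 5 passed newly (miR-317-3p in both, miR-8-3p, miR-9c-5p and miR-1012-5p) and 2 no longer did (miR-11-5p and miR-13b-2-5p). In the test of any difference miR-277-5p, miR-14-5p, miR-306-3p, miR-308-3p and bantam-5p no longer passed (edgeR adjusted p from 0.0592 to 0.0859). The minimum of 20 reads moved nothing, since all 110 arms passed it, and the half-life ratio had no value at a mean of at least 1000 reads. T coverage reached down to 35 in an arm's window, and on simulated data a fold of 2 was recovered in 2 of 20 arms for abundance and 0 of 20 for conversion. The conversion simulation held no shift between replicates.

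For abundance between 24 h and 5 min, 6 arms became 2 with DESeq2's size factors and 2 with bantam-3p left out. For any difference among groups, 9 arms became 4 with the replicate block, 35 with DESeq2's test and 17 with labelled libraries and the block. With the block and without the second no-s4U library the counts were 24 for any difference, 18 between 24 h and no s4U and 17 between 24 h and 5 min. Leaving out 1 library at a time gave 1 to 60 for any difference, 2 to 70 between 24 h and no s4U and 1 to 14 between 24 h and 5 min.

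Arms with conversion above no s4U numbered 18 at 5 min and 65 at 30 min with a pseudocount of 0.0001, and 0, 7, 26, 30 and 50 from 5 min to 3 h with 0.01. They numbered 21 at 5 min and 69 at 30 min with the replicate block, and 2 at 5 min with all read positions. The T>C read share gave 20 at 5 min, 75 at 30 min and 82 at 60 min. The quasi-binomial model gave 0, 0, 0, 0 and 0 from 5 min to 3 h and 40, 49 and 55 from 6 h to 24 h. Leaving out 1 library gave 0 to 4 at 5 min, 24 to 37 at 15 min, 33 to 44 at 30 min, 38 to 56 at 60 min, 71 to 100 at 3 h, 91 to 102 at 6 h, 101 to 105 at 12 h and 102 to 107 at 24 h.

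The median half-life of 16.7 h became 23.8 h with 1 plateau for all arms (24 determined), 9.99 h up to 12 h (22), 7.76 h with the merged tables (96), 7.38 h with no R2 minimum (95), 7.86 h with a plateau for each replicate (92) and 13.9 h with the T>C read share (45). Without 1 replicate it was 6.86 to 7.98 h with 74 to 91 determined. The log2 guide to passenger half-life ratio was -0.74 with 1 plateau for all arms (1 precursor), 1.51 with the T>C read share (1 precursor), 3.98 with a plateau for each replicate (31 precursors) and 3.94 to 4.03 without 1 replicate. The correlation of half-life with abundance, 0.193, turned to -0.0880 with 1 plateau for all arms (permutation p = 0.681).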

Other observations

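The test of arms made in like numbers and the test of T tails by arm name were chosen before their results were seen, while the test of T tails by place in the hairpin and the arms singled out by half-life, mismatch or T share were chosen after their values were seen.

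Not every passenger had a short half-life. Of 11 arms above 48 h with a plateau for each replicate, 9 were guides and the rest were passengers, which are not among those named below. With a plateau for each replicate, half-lives of several hours were fitted to the passengers miR-2279-3p (10.4 h, SE 2.90; 8.83 and 14.6 h in the first and second replicate), miR-9b-3p (8.02 h, SE 1.51; 8.37 and 6.63 h), miR-307a-5p (5.81 h, SE 0.902; 6.24 and 4.92 h) and miR-8-5p (4.43 h, SE 0.956; 4.64 and 3.64 h), and 1.31 h (SE 0.226) to miR-2b-2-5p. miR-190-3p, miR-276b-3p and miR-281-1-5p also had fitted values above 1 h, but none was determined in the second replicate. Among the 57 determined guides, miR-276b-5p (0.770 h, first 18 nt shared with miR-276a-5p), miR-12-5p (1.74 h, SE 0.188; 1.78 and 1.60 h), miR-7-5p (2.72 h, SE 0.305; 2.72 and 2.75 h), miR-308-3p (3.03 h, SE 0.442) and miR-190-5p (3.04 h) were the shortest-lived. The fit takes arm levels as constant, but miR-12-5p and miR-190-5p fell between 5 min and 24 h (log2 change -1.16 and -1.87). Changes of miR-7-5p (-0.89), miR-308-3p (0.92) and miR-276b-5p (0.53) did not pass. These fitted values therefore need not be lifetimes. In some passengers conversion was lower at 24 h than at 60 min in each replicate, without a test. The means were 9.82% at 60 min and 6.90% at 24 h in miR-14-5p, 9.08% and 6.24% in miR-275-5p, and 6.57% and 4.94% in miR-965-5p.

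Guides outnumber their passengers in the no-s4U libraries by definition, since the guide was chosen there. The median log2 ratio in those libraries was 4.25 over 33 precursors. A candidate explanation of its size is that both arms are made in like numbers and decay at different rates. Among molecules labelled within 15 min the median log2 guide to passenger ratio was 0.52 (interquartile range 0.02 to 1.18), 21 of the 33 precursors lay within 1 of 0, and in 8 the passenger was ahead. The ratio of all molecules exceeded that of labelled ones by a mean of 3.29 (SE 0.29, sign-flip permutation p = 1e-05). The choice of guide tilts this test toward such an excess. The ratio of all molecules also comes from the no-s4U libraries, the second of which stood apart, and not from the labelled libraries. The labelled ratio was 1.25 at 30 min (33 precursors), 1.62 at 60 min (37) and 4.34 at 24 h (37), over the precursors that entered at each time. The highest labelled log2 ratios at 15 min were those of miR-9c (5.21), miR-184 (2.56) and miR-308 (2.48), and the lowest those of miR-306 (-1.38) and miR-14 (-1.38). The count allows for the number of T of an arm, but loss within the first 15 min would not be seen, so like production remains a hypothesis.

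Mirtron 3p arms may be tailed with U more often than other 3p arms. T at reference positions other than T, from position 20 on, had a median of 3.83% in 6 mirtron 3p arms and 0.839% in 50 others, a difference of 2.99 points (permutation p = 0.0334). With arms named 5p that start in the 3′ part of their hairpin counted as well, miR-1009-5p (0.412%) among them, the medians were 3.82% in 7 mirtron arms and 0.839% in 52 others (permutation p = 0.0231). Among mirtrons the share was 15.98% ± 1.64 in miR-1008-3p (SD over 18 libraries), 5.10% in miR-1007-3p, 3.83% in miR-1003-3p, 3.82% in miR-1012-3p, 1.72% in miR-1006-3p and 0.526% in miR-1016-3p. The highest shares of all were in other arms: miR-995-3p (88.8% ± 3.92), miR-2279-3p (66.7% ± 47.1), miR-278-3p (63.3% ± 7.45) and miR-4962-3p (56.6%), followed after miR-1008-3p by miR-980-3p (12.7%) and miR-998-3p (12.0%). The share of miR-2279-3p was 33.3% in the first replicate and 100% in the second. Its SD equals that of these values alone, so it appears to rest on few libraries. Whether these T are added or encoded was not tested.

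In 8 arms, 23 sites differed from the reference in more than 1% of reads in all 18 libraries. Medians over libraries were 51.8% for T12G and 51.6% for T13C in miR-13a-3p, 77.9% for A10T in miR-276b-3p, 99.0% for T3A in miR-303-5p, 97.3% for T7A and 96.9% for G11A in miR-4962-3p, 99.8% for T10C and 99.0% for C13T in miR-4962-5p, 99.8% for C11T in miR-986-5p, 100% for C2G, A11C and T15G in miR-4940-5p, and 23.1% for G9A and 21.2% for A6G in miR-4968-3p.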
